A study of Mus musculus with 16 samples.

How the data were processed

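RNA recovered by immunoprecipitation from cytoplasmic extracts of C2C12 mouse myoblasts was measured on 16 Illumina mouse bead arrays. Per the labels, extracts came from cells in growth medium (GM) or differentiation medium (DM) and were incubated with anti-MYF5 or with control IgG, which gives 4 groups of 4 replicates. Per the labels' protocols, the precipitated RNA was amplified from an oligo-dT primer and labelled with biotin. Groups were taken from the sample titles. Nothing in the labels says whether the 4 replicates were separate cultures, so every p-value of a probe measures the spread between these samples only.

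The deposited table holds, per the file headers, a signal intensity and a detection p-value for each of 25697 probes on each array. GenomeStudio 2011.1 produced them, per the submitters' processing notes, and the intensities are not normalized between arrays. The deposited detection p-value compares a probe with the negative control beads of its own array. The deposited series values are a score without units. They were checked against the signals and equal the z-score of the log10 signal over all probes of an array, to within 5.0e-10. Their array medians lay between -0.55 and -0.51. Neither file states a chip or slide.

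Signals were background-corrected by normal-exponential convolution, with the control distribution inferred from the detection p-values, an offset of 16, quantile normalization between arrays and log2 transformation (limma 3.58.1, R 4.3.3). Probes were tested when detected at p under 0.05 on at least 4 of the 16 arrays, which kept 13884 probes. One linear model over all 16 arrays, with 12 residual degrees of freedom, gave every comparison (lmFit and eBayes with an intensity trend). The comparisons were MYF5 over IgG in GM, MYF5 over IgG in DM, the DM minus GM difference between those changes, DM over GM in IgG, and DM over GM in MYF5. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over all probes tested, at a threshold of 0.05. Because quantile normalization gives every array the same distribution, a change is relative to the other RNAs on the array.

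Gene symbols came from the platform annotation, updated through the Entrez identifier for 23962 probes and the accession for 9, with GRCm38.p6 used for names only. A further 7 probes kept the annotation's symbol. In all 23978 probes had 1 gene symbol, 0 had several and 1719 had none. The tested probes covered 9429 genes. For gene-level counts and lists a gene stands by its probe with the highest mean log2 signal. Where a probe was not detected on any array of the dimmer group, its fold is printed as a lower bound. That bound sets the brighter group's mean against the mean, per array, of the higher of the lowest detected signal and the probe's own signal.

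Genes were named by a rule set before the data were examined, as were the 25 gene lists and the tests of the comparisons and lists. Some tests of explanations were chosen after the results were seen, and are named where they are given. The rule takes, for each comparison, the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called probes. They had to be detected on all 4 arrays of a compared group, with the values of one group all above those of the other except for the DM minus GM difference. Up to 2 more genes come from each list past its test, in the list's direction, without the demand that values do not overlap. Ccnd1 and Myf5 are always given.

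The lists cover myogenic transcription regulators, sarcomere and excitation-contraction genes, other muscle differentiation genes, G1 cyclins with their kinases, inhibitors and pocket proteins, S phase and mitosis genes, histones, cytosolic ribosomal proteins, translation factors, RNA-binding regulators of mRNA fate, the spliceosome, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, extracellular matrix, the secretory pathway, immediate early and stress genes, long noncoding RNAs, the proteasome, glycolysis, cholesterol synthesis, housekeeping genes, the actin cytoskeleton, and 4 sets of markers of other cell types. The 21 lists with at least 5 tested members were tested with limma's camera at a correlation of 0.01, and again with an estimated correlation. Camera compares the changes of a list's genes with those of the other tested genes. At a correlation of 0.01 it treats genes as nearly independent, so its small p-values rest on the number of genes as well as on the arrays. limma's fry was run beside it and tests whether a list's genes move, on balance, in 1 direction.

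On simulated data the GM comparison recovered 96 of 100 probes planted with a log2 change of 1 and 39 of 100 planted with 0.5, with 5 false calls among 13884 probes. The DM minus GM difference recovered 75 of 100 and 12 of 100, with 3 false calls. The simulated noise was independent between probes and few probes were changed. Simulated values did not pass through background correction or normalization, so these rates need not hold for the real arrays. Ccnd1 also had an exact two-sided permutation test of 4 against 4 arrays, whose smallest possible p is 0.0286.

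Alternatives were no background correction, an offset of 50, median scaling, no scaling and cyclic loess between arrays, the deposited z-scores, no probe filter, a stricter filter of detection p under 0.01 on 8 arrays, one probe per gene, no intensity trend, array weights, only the groups compared, the replicate number as a fixed or random block, and leaving out each array. The deposited values and z-scores made from the signals were planned as separate alternatives and are the same numbers, so they were run once. A block for the BeadChip was planned and not run, since no file names the chip. Added after the data were seen were a fit with the gap between Actb probes as a covariate and a fit without the GM arrays numbered 4.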

Results

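RNA recovered with an antibody to MYF5, a basic helix-loop-helix transcription factor of the muscle lineage, was measured in C2C12 cells. This mouse myoblast line stops dividing and fuses into myotubes when serum is lowered. Cytoplasmic extracts of cells in growth medium (GM) or differentiation medium (DM) were precipitated with anti-MYF5 or with control IgG, which recovers RNA nonspecifically. Each of the 4 groups had 4 arrays. RNA from before precipitation was not analysed here, so recovery could not be set against abundance in the extract. The series title names Ccnd1, the mRNA for cyclin D1, which drives cells through G1.

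Mean signal per array ranged from 324 to 581, and between 46.4% and 50.9% of the 25697 probes were detected on each. Detection was 47.8% ± 1.21 (SD, n = 4) for GM with IgG, 48.2% ± 1.23 for GM with MYF5, 50.2% ± 0.583 for DM with IgG and 50.4% ± 0.470 for DM with MYF5. Normalized log2 values of arrays from the same group correlated across probes at r of 0.977 to 0.996, and those of arrays from different groups at 0.841 to 0.972. The number of arrays limits the precision of every comparison. The 5 probes for Actb, the gene for beta-actin, did not move together. The log2 gap between ILMN_2698799 and ILMN_2588055, its probes with the highest and lowest mean over all arrays, was 6.42 ± 1.53 (SD, n = 4) for GM with IgG, 3.94 ± 0.52 for GM with MYF5, 4.73 ± 0.81 for DM with IgG and 2.61 ± 0.76 for DM with MYF5. This gap was thus narrower with anti-MYF5 in both media, and nothing measured here ties it to RNA quality or to priming. The Myf5 probe itself was detected on 1 of 16 arrays, with signals of 54.2 to 83.3, and was not tested.

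**Figure D1:**
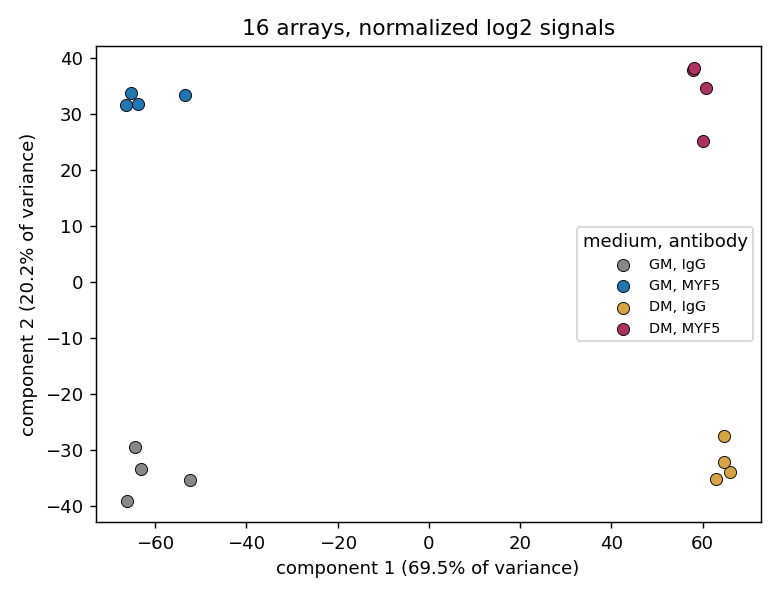
Position of the 16 arrays on the first 2 principal components of the normalized log2 signals, with 1 point per array coloured by medium and antibody. Component 1, with 69.5% of the variance, separated the media and component 2, with 20.2%, separated MYF5 from IgG.

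The comparison of MYF5 with IgG in growth medium asks which RNAs anti-MYF5 recovers beyond background in dividing myoblasts. Ccnd1 was higher with anti-MYF5 at all 3 of its probes. The brightest, ILMN_1221503, had a mean signal of 15071 ± 3155 (SD, n = 4) against 10380 ± 2803 with IgG, a 1.46-fold difference in the normalized values (log2 fold change 0.55, SE 0.12, adjusted p = 9.4e-04). The others, ILMN_2601471 and ILMN_2669793, differed by 0.44 (adjusted p = 1.9e-03) and 0.76 (adjusted p = 0.015). Normalized values of every MYF5 array lay above those of every IgG array at each probe, which gives an exact two-sided permutation p of 0.0286, the smallest this design allows. For the brightest probe the call ended with median scaling (0.43, adjusted p = 0.056) and cyclic loess (0.19, adjusted p = 0.19), and its sign turned in the deposited z-scores (-0.04 in z units, adjusted p = 0.76). ILMN_2601471 lost its call in the same 3 settings, while ILMN_2669793 kept it under all 5 scalings. The brightest probe stood at percentile 69 among the 200 probes nearest to it in mean signal.

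Around Ccnd1, RNAs of the G1 machinery were higher with anti-MYF5 and those of energy production and protein turnover were lower. Of 23 tested genes for G1 cyclins, their kinases, inhibitors and pocket proteins, 14 were higher and 0 lower (14 and 1 adjusted over the list alone), with a median log2 fold change of 0.48. Cdk2, the kinase that pairs with cyclin E, was higher by 1.00 (SE 0.10) and Tfdp1, the DNA-binding partner of E2F factors, by 0.86 (SE 0.14). The list passed camera at adjusted p = 0.0078, and had adjusted p = 0.11 with an estimated correlation. Among immediate early and stress genes 11 of 22 were higher and 2 lower (the same counts adjusted over the list alone), with a median of 0.42. Gadd45a, a growth arrest gene, was higher by 1.23 (SE 0.24; 0.47 and adjusted p = 0.13 with the Actb gap as a covariate), and Egr2, a zinc finger factor induced by serum, by 0.99 (SE 0.13). That list had adjusted p = 0.045, and adjusted p = 0.29 with an estimated correlation. It missed the threshold with no background correction (0.055), offset 50 (0.054), median scaling (0.060), no scaling (0.067) and z-scores (0.14).

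Subunits of the respiratory chain and ATP synthase were lower as a group in growth medium. Of 70 nuclear-encoded oxidative phosphorylation genes, 58 were lower and 1 higher (59 and 1 adjusted over the list alone), with a median log2 fold change of -1.13. Atp5e and Atp5o, subunits of ATP synthase, changed by -2.79 (SE 0.18) and -2.25 (SE 0.15). The list had adjusted p = 2.1e-23, and adjusted p = 0.11 with an estimated correlation. Of 28 proteasome subunits, 25 were lower and 0 higher (25 and 0 adjusted over the list alone), with a median of -0.87. Psmc1 and Psmd4, both of the regulatory particle, changed by -1.44 (SE 0.10) and -1.35 (SE 0.12). The proteasome list had adjusted p = 3.5e-10, and adjusted p = 0.11 with an estimated correlation. Of 59 cytosolic ribosomal protein genes, 39 were lower and 3 higher (39 and 4 adjusted over the list alone), with a median of -0.59. Rpl28 and Rpl29, of the large subunit, changed by -2.01 (SE 0.11) and -1.89 (SE 0.12). The ribosomal list had adjusted p = 1.7e-11, and adjusted p = 0.11 with an estimated correlation. These 3 lists moved beside the narrower Actb gap of 3.94 with anti-MYF5 against 6.42 with IgG.

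Lists for chromatin, splicing, sugar breakdown and contraction also passed camera in the lower direction, though not with an estimated correlation. Histone genes, whose probes can detect several near-identical copies, were lower for 21 of 31 and higher for 2 (21 and 4 adjusted over the list alone), with a median of -0.75. RNA was amplified from an oligo-dT primer, and how far it primes histone mRNAs was not measured in either medium. The probes assigned to H2ac21 and H2ac11 changed by -2.81 (SE 0.15) and -2.31 (SE 0.16), and the list had adjusted p = 2.9e-05 (adjusted p = 0.35 with an estimated correlation). Of 38 spliceosome genes, 19 were lower and 7 higher (the same adjusted over the list alone), with a median of -0.37. Snrpd2, a core Sm protein, and Snrpc, of the U1 particle, changed by -1.95 (SE 0.15) and -1.51 (SE 0.14). The spliceosome list had adjusted p = 0.0098, and adjusted p = 0.35 with an estimated correlation. Of 16 glycolysis genes, 6 were lower and 0 higher (the same adjusted over the list alone), with a median of -0.21, led by Aldoa at -1.87 (SE 0.15) and the muscle enolase Eno3 at -1.79 (SE 0.16). The glycolysis list had adjusted p = 0.0098, and adjusted p = 0.40 with an estimated correlation. Sarcomere and excitation-contraction genes were lower for 10 of 41 and higher for 1 (the same adjusted over the list alone), with a median of -0.05 and a mean of -0.36. The 12 members detected on all 8 GM arrays had a median of -0.78, and the other 29 had one of -0.04. Tnnt1 and Mylpf, a slow troponin and a fast myosin light chain, changed by -1.82 (SE 0.47) and -1.75 (SE 0.29), and were detected on 2 and 1 of the 4 MYF5 arrays. Both were highest on the GM arrays numbered 4, and Tnnt1 stood at -1.22 without GM IgG array 4 and at -2.35 without GM MYF5 array 4. By number, Tnnt1 was 4.51, 4.94, 4.41 and 6.74 on the GM MYF5 arrays. It was higher on each GM IgG array of the same number, at 5.99, 6.83, 6.21 and 8.86. That list had adjusted p = 0.038, adjusted p = 0.71 with an estimated correlation, and missed the threshold with no background correction (0.082) and offset 50 (0.057).

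By the naming rule the largest single changes in growth medium fell outside these lists for the most part. Outside the rule, since values overlapped between groups, the Actb probes ILMN_2588055 and ILMN_2846865 were higher by 2.24 and 2.18. Rfc1, the large subunit of the clamp loader used in DNA replication, was 4.45-fold higher with anti-MYF5 (log2 fold change 2.15, SE 0.12, adjusted p = 7.0e-11). Mreg, a melanosome transport protein, was 3.85-fold higher, Gatad1 and Tmem38b, a potassium channel of the endoplasmic reticulum, 3.84-fold, and the G protein subunit Gna12 and Arl2bp 3.74-fold. Bend6, Pxdc1, Ykt6 and Stx2, the last pair SNARE proteins of membrane fusion, were 3.64-fold, 3.63-fold, 3.53-fold and 3.50-fold higher. At the other end Smarcal1, an annealing helicase at stalled replication forks, was 7.20-fold lower (log2 fold change -2.85, SE 0.15, adjusted p = 5.3e-11). S100a13, Ddt and Atrip, which carries the checkpoint kinase ATR to DNA, were 6.03-fold, 5.12-fold and 4.85-fold lower. Probes for Hba-a1 and Sprr2a1, both members of families of near-identical genes, were 4.91-fold and 4.86-fold lower.

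The remaining lists did not pass camera in growth medium. Other muscle differentiation genes (median -0.11, 1 higher and 4 lower of 19, 1 and 3 adjusted over the list alone) had adjusted p = 0.28, myogenic transcription regulators (0.12, 4 and 0 of 14, the same adjusted over the list alone) 0.24, and translation factors (-0.15, 9 and 16 of 36, the same adjusted over the list alone) 0.16. S phase and mitosis genes (median under 0.01 in size, mean -0.10, 7 and 11 of 34, 7 and 12 adjusted over the list alone), extracellular matrix (-0.08, 3 and 6 of 36, the same adjusted over the list alone) and actin cytoskeleton genes (-0.18, 7 and 10 of 29, 7 and 11 adjusted over the list alone) each had 0.41. RNA-binding regulators of mRNA fate (0.01, 5 and 4 of 29) and cholesterol synthesis (0.17, 5 and 5 of 17) had 0.93, secretory genes 0.52 (median 0.02, mean -0.13), and housekeeping genes 0.64 (median -0.04). Markers of adipocytes (5 tested, median -0.12, mean 0.11) had 0.82 and those of bone and cartilage (6 tested) 0.93. Markers of blood (2 of 3 lower) and of neurons, liver and epithelium (1 higher and 1 lower of 3) had too few members for the test. Mitochondrially encoded transcripts and long noncoding RNAs had 0 members among the named probes. Among lists not past camera, unadjusted fry p was 7.1e-06 for translation factors and 2.5e-04 for myogenic regulators. It was 0.023 for other muscle genes, 0.042 for secretory genes and 0.044 for actin genes. The S phase, matrix, RNA-binding, cholesterol, housekeeping and adipocyte lists had fry p of 0.11 to 0.75.

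Over all 13884 probes, 3705 were higher and 3072 lower with anti-MYF5 in growth medium, or 48.8%, and 523 and 817 of these differed at least 2-fold. By gene, 2481 of 9429 were higher and 2110 lower, and of 2587 genes with several probes 51 had opposite calls. The split rested on the scaling. Median scaling gave 4628 higher and 1637 lower, with the median of all genes shifted by 0.19, and no scaling gave 5588 and 1121, with a shift of 0.32. Relative to that shift the oxidative phosphorylation, proteasome and ribosomal lists stayed lower under all 5 scalings. Their medians were -1.22 to -1.17, -0.92 to -0.87 and -1.02 to -0.62 on the log2 scale, and -0.73, -0.60 and -0.71 in z units in the z-scores.

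**Figure D2:**
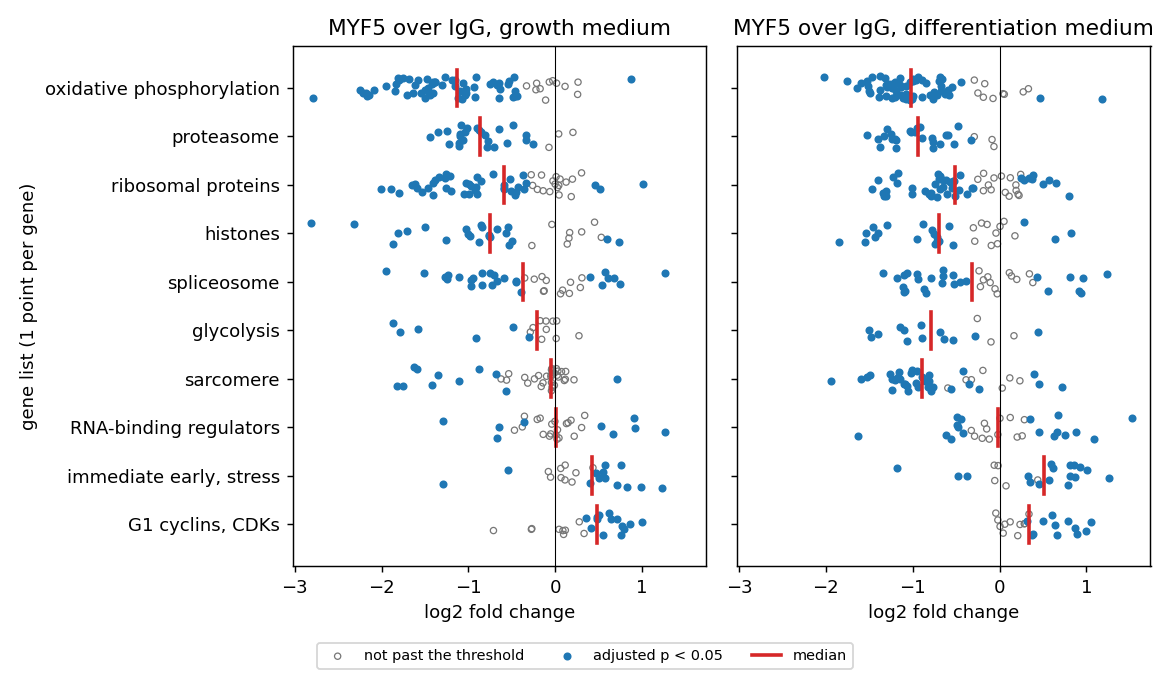
Log2 fold change of MYF5 over IgG for each tested gene of 10 lists in GM (left) and DM (right), with filled points past the threshold and red bars at list medians. Oxidative phosphorylation lay at medians of -1.13 and -1.02 and G1 cyclins with their partners at 0.48 and 0.34.

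In differentiation medium the same comparison asks what anti-MYF5 recovers once cells have been switched toward myotubes. Ccnd1 was again higher with anti-MYF5, at a level far below that in growth medium. The brightest probe had a mean signal of 1814 ± 279 (SD, n = 4) against 1338 ± 52.3, a 1.42-fold difference in the normalized values (log2 fold change 0.50, SE 0.12, adjusted p = 1.8e-03). The other probes differed by 0.46 (adjusted p = 1.2e-03) and 0.74 (adjusted p = 0.016). The exact two-sided permutation p was 0.0286 for the brighter pair and 0.114 for the dimmest. The call at the brightest probe ended with median scaling (0.42, adjusted p = 0.063) and with no scaling (0.44, adjusted p = 0.092), and the probe stood at percentile 73 among its 200 neighbours in signal. The other probes lost their calls in the same settings, at adjusted p = 0.13 and 0.17 for ILMN_2601471 and 0.057 and 0.063 for ILMN_2669793. Every Ccnd1 probe kept its DM call with cyclic loess and with z-scores.

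**Figure D3:**
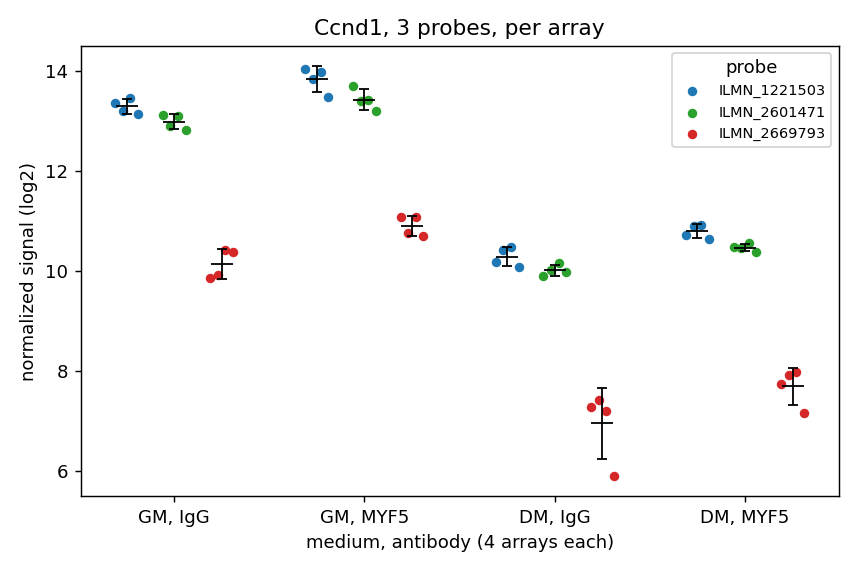
Normalized log2 signal of the 3 Ccnd1 probes on each array by medium and antibody, with 1 point per array and bars for mean and SD (n = 4). At ILMN_1221503 the means were 13.30 for IgG and 13.85 for MYF5 in GM, and 10.30 and 10.80 in DM.

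Myogenic regulators and G1 genes were higher with anti-MYF5 in differentiation medium, while contractile and metabolic genes were lower. Of 14 myogenic transcription regulators 6 were higher and 0 lower (the same adjusted over the list alone), with a median of 0.23. Both named members are repressors of myogenic bHLH factors: Msc, musculin, was higher by 0.81 (SE 0.17) and Id2, an inhibitor of DNA binding, by 0.79 (SE 0.16). The list had adjusted p = 0.021, and adjusted p = 0.16 with an estimated correlation. G1 cyclins and partners were higher for 12 of 23 and lower for 0 (the same adjusted over the list alone), with a median of 0.34. E2f5 and Tfdp1 were higher by 1.05 (SE 0.16) and 1.00 (SE 0.14), and the list had adjusted p = 0.0027 (adjusted p = 0.14 with an estimated correlation). Immediate early and stress genes were higher for 14 of 22 and lower for 3 (15 and 3 adjusted over the list alone), with a median of 0.52. Jun, a subunit of AP-1, was higher by 1.26 (SE 0.16) and Dusp1, a MAP kinase phosphatase, by 1.01 (SE 0.10). That list had adjusted p = 0.013, and adjusted p = 0.15 with an estimated correlation.

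Sarcomere and excitation-contraction genes were lower with anti-MYF5 for 31 of 41 and higher for 3 in differentiation medium (the same adjusted over the list alone), with a median of -0.89. Myl2, a slow myosin light chain, was 3.84-fold lower and Myh4, a fast myosin heavy chain, 3.02-fold. The sarcomere list had adjusted p = 1.5e-07, and adjusted p = 0.18 with an estimated correlation. Other muscle differentiation genes were lower for 11 of 19 and higher for 2 (11 and 3 adjusted over the list alone), with a median of -0.53. Eno3 changed by -1.49 (SE 0.16) and the muscle creatine kinase Ckm by -1.27 (SE 0.14), and the list had adjusted p = 0.039 (adjusted p = 0.30 with an estimated correlation). Of 16 glycolysis genes 12 were lower and 1 higher (13 and 1 adjusted over the list alone), with a median of -0.79, led by Aldoa at -1.51 (SE 0.15) and Eno3. The glycolysis list had adjusted p = 2.1e-04, and adjusted p = 0.18 with an estimated correlation. Actin cytoskeleton and adhesion genes were lower for 16 of 29 and higher for 4 (the same adjusted over the list alone), with a median of -0.35. Myh10, a nonmuscle myosin, and Myl6, its light chain, changed by -1.42 (SE 0.19) and -1.35 (SE 0.15), and the list had adjusted p = 0.016 (adjusted p = 0.25 with an estimated correlation).

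The respiratory chain, the proteasome and the translation apparatus were lower with anti-MYF5 in differentiation medium as well. Oxidative phosphorylation genes were lower for 59 of 70 and higher for 2 (59 and 3 adjusted over the list alone), with a median of -1.02. Atp5e and the muscle cytochrome oxidase subunit Cox8b changed by -2.02 (SE 0.18) and -1.75 (SE 0.15), and the list had adjusted p = 1.0e-18 (adjusted p = 0.14 with an estimated correlation). Of 28 proteasome subunits 25 were lower and 0 higher (the same adjusted over the list alone), with a median of -0.93, led by the ATPases Psmc4 at -1.52 (SE 0.15) and Psmc3 at -1.40 (SE 0.13). The proteasome list had adjusted p = 5.6e-11, and adjusted p = 0.14 with an estimated correlation. Ribosomal proteins were lower for 35 of 59 and higher for 9 (the same adjusted over the list alone), with a median of -0.51, led by Rpl29 at -1.47 (SE 0.12) and Rpl28 at -1.40 (SE 0.11). The ribosomal list had adjusted p = 4.3e-05, and adjusted p = 0.25 with an estimated correlation. Translation factors were lower for 21 of 36 and higher for 7 (the same adjusted over the list alone), with a median of -0.46. Eif6, which keeps ribosomal subunits apart, and Eif3a, the scaffold of initiation factor eIF3, changed by -1.36 (SE 0.10) and -1.30 (SE 0.13), and the list had adjusted p = 0.013 (adjusted p = 0.14 with an estimated correlation). The Actb gap was 2.61 with anti-MYF5 against 4.73 with IgG beside these lists.

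Nuclear gene groups were lower in differentiation medium too. Histone genes were lower for 18 of 31 and higher for 3 (the same adjusted over the list alone), with a median of -0.70, led by the probes assigned to H2ac22 at -1.85 (SE 0.15) and H2ac20 at -1.54 (SE 0.14). The histone list had adjusted p = 6.5e-04, and adjusted p = 0.30 with an estimated correlation. Of 34 S phase and mitosis genes 16 were lower and 3 higher (the same adjusted over the list alone), with a median of -0.36. Mcm6, of the replicative helicase, and Tyms, thymidylate synthase, changed by -1.28 (SE 0.12) and -1.04 (SE 0.15), and the list had adjusted p = 0.0066 (adjusted p = 0.30 with an estimated correlation). Spliceosome genes were lower for 19 of 38 and higher for 7 (the same adjusted over the list alone), with a median of -0.31. Snrpd2 and the helicase Snrnp200 changed by -1.34 (SE 0.15) and -1.18 (SE 0.12), and the list had adjusted p = 0.023 (adjusted p = 0.30 with an estimated correlation).

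The largest single change upward in differentiation medium was that of Arl2bp, which was 4.53-fold higher with anti-MYF5 (log2 fold change 2.18, SE 0.15, adjusted p = 3.4e-09). Plau, the urokinase protease, was 3.82-fold higher, the FGF receptor adaptor Frs3 3.78-fold, Tmem80 3.74-fold and the matricellular growth factor Ccn2 3.73-fold. Usp12, Mzt1, Gatad1, the homeobox gene Hoxa9 and the NF-kappaB regulator Nfkbiz were between 3.41-fold and 3.63-fold higher. Beyond list members already named, Chmp2a, an ESCRT subunit, was 3.36-fold lower, the electron transfer flavoprotein Etfb 3.34-fold, Bloc1s1 3.31-fold and the cardiac myosin gene Myh6 3.22-fold. The probes for Eno1b and H2ac10, which have near-identical copies, were 3.31-fold and 3.29-fold lower.

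Lists not past camera in differentiation medium were extracellular matrix (median -0.15, 6 higher and 13 lower of 36, the same adjusted over the list alone, adjusted p = 0.29), RNA-binding regulators (median -0.02, mean 0.05, 9 and 8 of 29, the same adjusted over the list alone, 0.89) and the secretory pathway (-0.07, 7 and 8 of 26, 7 and 9 adjusted over the list alone, 0.75). Cholesterol synthesis (0.02, 6 and 6 of 17), housekeeping genes (median 0.01, mean -0.01, 4 and 2 of 10) and the adipocyte and bone markers had adjusted p of 0.98, 0.96, 0.89 and 0.98. Over all probes 3713 were higher and 3633 lower, or 52.9%, and 617 and 776 differed at least 2-fold. The balance turned with median scaling (2406 higher and 3510 lower), no scaling (2177 and 2980) and cyclic loess (3630 and 3736). By gene 2609 were higher and 2507 lower, with opposite calls between probes of 42 genes.

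The changes in the 2 media ran in parallel across genes. Log2 fold changes of MYF5 over IgG correlated between GM and DM at Pearson r of 0.832 and Spearman rho of 0.820 over 9429 genes, which are not independent replicates. Of the genes called, 1859 were higher in both media, against 686 for independent lists, and 1632 were lower in both, against 561. Opposite calls were made for 30. No array is shared between these comparisons.

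The DM minus GM difference asks which RNAs anti-MYF5 recovered differently in the 2 media, each against its own IgG. Ccnd1 showed no detectable difference (log2 difference -0.04, SE 0.18, adjusted p = 0.92). On the positive side the checkpoint gene Atrip differed by 1.77 (SE 0.23), the helicase Blm by 1.75 (SE 0.20) and Smarcal1 by 1.73 (SE 0.21). The embryonic myosin light chain Myl4 differed by 1.53 (SE 0.13), the golgin Gcc2 by 1.51 (SE 0.22) and the Notch ligand Jag1 by 1.41 (SE 0.22). Jag1 was detected on 1 of the 8 GM arrays. Ifitm1 and the probes for Hba-a1, H3c10 and H2ac21 differed by 1.56, 1.71, 1.70 and 1.27, and Ifitm1 and H3c10 were detected on 0 of the 8 DM arrays, so that no DM change was measurable for them. On the negative side Chtf18, an alternative clamp loader, differed by -1.91 (SE 0.19), the actin crosslinker Actn4 by -1.75 (SE 0.27), Rfc1 by -1.62 (SE 0.18) and the motor Myo5a by -1.52 (SE 0.27). Myl2 (-1.93, SE 0.20), Myh6 (-1.65), Itgb1bp2 (-1.59), Cox8b (-1.58), Tceal5 (-1.57) and Myh4 (-1.56) were also negative, and their probes were detected on 0 of the 8 GM arrays, so that no GM change was measurable for them.

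By list, the medians of ribosomal and respiratory genes lay above 0 in this difference, and contractile genes near the floor in GM lay below it. Sarcomere genes were lower for 16 of 41 and higher for 3 (18 and 5 adjusted over the list alone), with a median of -0.47 (adjusted p = 6.0e-07, and adjusted p = 0.52 with an estimated correlation). The 29 not detected on all 8 GM arrays had a mean of -0.67, and the other 12 had a mean of 0.27 (SE 0.28), with 3 higher and 1 lower. Ribosomal proteins were higher for 10 of 59 and lower for 0 (15 and 0 adjusted over the list alone), with a median of 0.27, among them Rps13 at 0.78 (SE 0.18) and Rpl14 at 0.76 (SE 0.19). The ribosomal list had adjusted p = 4.9e-07, and adjusted p = 0.52 with an estimated correlation. Oxidative phosphorylation genes were higher for 10 of 70 and lower for 3 (19 and 5 adjusted over the list alone), with a median of 0.26, among them Ndufa4 at 1.06 (SE 0.21) and Atp5g2 at 0.97 (SE 0.25). The oxidative phosphorylation list had adjusted p = 8.1e-04, adjusted p = 0.80 with an estimated correlation, and fry p = 0.10, where the other 4 lists past camera had fry p of 0.0034 to 0.029. S phase and mitosis genes were lower for 5 of 34 (10 lower and 1 higher adjusted over the list alone), with a median of -0.25, among them Cdc20, the activator of the anaphase promoting complex, at -0.99 (SE 0.16) and Mcm5 at -0.97 (SE 0.19). That list had adjusted p = 0.015, and adjusted p = 0.80 with an estimated correlation. Actin cytoskeleton genes were lower for 5 of 29 (7 adjusted over the list alone), with a median of -0.15, among them Myh10 at -1.19 (SE 0.27). The actin list had adjusted p = 0.019, and adjusted p = 0.52 with an estimated correlation, and in the z-scores its median relative to all probes turned to 0.02 (adjusted p = 0.83).

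In all, 322 probes were higher and 465 lower in the DM minus GM difference, or 5.67%, and 35 and 102 differed at least 2-fold. By gene 234 were higher and 311 lower. The split turned on the scaling: median scaling gave 71 higher and 839 lower (shift of all genes -0.27), no scaling 39 and 1140 (shift -0.38), and cyclic loess 360 and 338. The total was 1358 without GM IgG array 4, which had the lowest mean signal, 1460 without both GM arrays numbered 4, and 439 without DM MYF5 array 2. The lists not past camera in this difference were other muscle genes (median -0.22, 2 higher and 6 lower of 19, the same adjusted over the list alone), histones (0.13), proteasome subunits (-0.12) and glycolysis (-0.04), each at adjusted p = 0.19, and translation factors (-0.11) at 0.18. Myogenic regulators (0.14) and secretory genes (0.16) had 0.41, spliceosome (0.07), immediate early (0.09) and housekeeping genes (0.17) 0.43, G1 genes (0.01), RNA-binding regulators (0.05) and extracellular matrix (-0.04) 0.92, and cholesterol synthesis (-0.03) and the adipocyte and bone markers 0.94. The S phase list missed the threshold with no background correction (0.14), offset 50 (0.11), no scaling (0.075) and z-scores (0.21), and Rps13, Rpl14, Ndufa4 and Atp5g2 with median scaling (0.10, 0.21, 0.063 and 0.12).

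The change from growth to differentiation medium in the IgG precipitate shows how background RNA followed the state of the cells. Contractile genes were higher in DM without exception, and genes of DNA replication and mitosis were lower without exception. All 41 sarcomere genes were higher (41 adjusted over the list alone), with a median log2 fold change of 6.08, or 5.85 with the 22 genes not detected in GM at their lower bound. Myh8 and Myh1, perinatal and fast myosin heavy chains not detected on any GM array, were at least 496-fold and at least 396-fold higher. All 19 other muscle genes were higher (19 adjusted over the list alone), with a median of 2.00, led by myoglobin, Mb, at 208-fold (log2 fold change 7.70, SE 0.13) and Chrng, the fetal acetylcholine receptor subunit, at 84.3-fold (6.40, SE 0.33). All 34 S phase and mitosis genes were lower (34 adjusted over the list alone), with a median of -2.46, led by the survivin gene Birc5 at -3.93 (SE 0.11) and thymidine kinase Tk1 at -3.77 (SE 0.13). The sarcomere, other muscle and S phase lists had adjusted p of 1.4e-31, 8.4e-12 and 1.7e-19, and each adjusted p = 0.0085 with an estimated correlation. Ccnd1 was 8.01-fold lower in DM (log2 fold change -3.00, SE 0.12, adjusted p = 6.5e-15).

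Matrix, glycolysis, ribosomal and splicing genes moved less between the media in the IgG precipitate. Of 36 extracellular matrix genes 24 were higher and 5 lower in DM (24 and 6 adjusted over the list alone), with a median of 1.07 (0.98 with 3 genes at their bound), led by the proteoglycan Dcn at 4.76 (SE 0.43) and Col1a1, which was at least 8.87-fold higher. The matrix list had adjusted p = 1.4e-04, and adjusted p = 0.20 with an estimated correlation. Of 16 glycolysis genes 14 were higher and 1 lower (the same adjusted over the list alone), with a median of 0.95, led by the muscle genes Pgam2, at least 75.7-fold higher, and Pfkm at 3.74 (SE 0.18). The glycolysis list had adjusted p = 7.2e-05, and adjusted p = 0.20 with an estimated correlation. Ribosomal proteins were lower for 48 of 59 and higher for 1 (the same adjusted over the list alone), with a median of -0.40, led by Rplp0 at -1.54 (SE 0.13) and Rpl13a at -1.38 (SE 0.11). The ribosomal list had adjusted p = 5.7e-06, and adjusted p = 0.27 with an estimated correlation. Spliceosome genes were lower for 28 of 38 and higher for 3 (the same adjusted over the list alone), with a median of -0.97, led by Lsm2 at -2.45 (SE 0.17) and Lsm3 at -2.13 (SE 0.13). The spliceosome list had adjusted p = 5.7e-06, and adjusted p = 0.092 with an estimated correlation.

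Among single genes in the IgG precipitate, the sarcomere genes Mylpf and Acta1 were 344-fold and 193-fold higher in DM. Tnnc2 and Actc1, also of the sarcomere, had fitted log2 changes of 8.85 and 8.40, but were detected on 1 of the 4 GM arrays, number 4, without which the values were 9.37 and 8.80. Myh4, Tnnt3 and the ion transport regulator Fxyd6, not detected on GM arrays, were at least 192-fold, 177-fold and 138-fold higher. Placental prolactin family probes were the furthest down, with Prl2c4 48.6-fold and Prl2c3 46.7-fold lower at probes that near-identical copies share. Slco4a1, detected on 1 of the 4 DM arrays, fell by 4.52 on the log2 scale. Blm was 21.3-fold lower, the cohesin protector Sgo1 18.8-fold, Igsf11 16.6-fold, the cell cycle factor Mybl2 15.8-fold and Cdca3 15.6-fold. The probes for H2ac11 and Hba-a1, the latter detected on 3 of the 4 DM arrays, were 16.8-fold and 16.4-fold lower. Over all probes 3979 were higher and 4740 lower, or 62.8%, and 1477 and 1413 differed at least 2-fold. With median scaling the split was 4459 to 2959, and with no scaling 4846 to 2162 (shift of all genes 0.19). By gene 2778 were higher and 3208 lower, and 50 genes had probes with opposite calls. The Actb gap was 4.73 in DM against 6.42 in GM.

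In the MYF5 precipitate the change from growth to differentiation medium had much the same shape. All 41 sarcomere genes were higher in DM (41 adjusted over the list alone), with a median of 5.29, or 5.10 with the 22 genes not detected in GM at their lower bound. Acta1, detected on all GM arrays, was 424-fold higher (log2 fold change 8.73, SE 0.21). Mylpf had a fitted log2 change of 9.58 (SE 0.29), but was detected on 1 of the 4 GM arrays. Of 19 other muscle genes 18 were higher and 0 lower (the same adjusted over the list alone), with a median of 2.18 (2.00 with 6 genes at their bound). Mb and Igf2, a growth factor of differentiating myoblasts, had fitted log2 changes of 6.88 and 6.85, each detected on 1 of the 4 GM arrays. All 34 S phase and mitosis genes were lower (34 adjusted over the list alone), with a median of -2.46, led by Mcm5 at -3.99 (SE 0.14) and Birc5 at -3.96 (SE 0.11). These lists had adjusted p of 2.1e-31, 1.1e-11 and 1.0e-21, and each adjusted p = 0.0067 with an estimated correlation. Ccnd1 was 8.26-fold lower (log2 fold change -3.05, SE 0.12, adjusted p = 5.5e-15).

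Matrix and glycolysis genes were higher in DM and spliceosome genes lower in the MYF5 precipitate. Of 36 matrix genes 23 were higher and 4 lower (the same adjusted over the list alone), with a median of 1.13, led by Dcn, detected on 3 of the 4 GM arrays, at 4.66 (SE 0.43) and Col6a1 at 2.88 (SE 0.20). The matrix list had adjusted p = 6.7e-05, and adjusted p = 0.16 with an estimated correlation. Of 16 glycolysis genes 10 were higher and 0 lower (the same adjusted over the list alone), with a median of 0.53, led by Pgam2, at least 29.1-fold higher, and Pfkm at 3.04 (SE 0.18). The glycolysis list had adjusted p = 3.3e-04, and adjusted p = 0.27 with an estimated correlation. Spliceosome genes were lower for 32 of 38 and higher for 1 (32 and 2 adjusted over the list alone), with a median of -0.73, led by Lsm2 at -2.07 (SE 0.17) and the splicing factor Srsf1 at -1.76 (SE 0.12). The spliceosome list had adjusted p = 3.8e-06, and adjusted p = 0.084 with an estimated correlation. Tnnc2, Myh8, Myh1 and Actc1, not detected on GM arrays with MYF5, were at least 254-fold, 242-fold, 227-fold and 204-fold higher, and Fxyd6 at least 93.1-fold. The myosin light chains Myl4 and Myl1 were 308-fold and 210-fold higher, and Tnnt1, detected on 2 of the 4 GM arrays, had a fitted log2 change of 7.66. Downward, Prl2c3 was 71.4-fold lower, Prl2c4 62.1-fold, Slco4a1 at least 50.3-fold, Igsf11 24.8-fold, Mybl2 22.7-fold, Chtf18, detected on 3 of the 4 DM arrays, 19.3-fold, Cdca3 19.1-fold and the mitotic gene Gtse1 16.7-fold.

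Over all probes of the MYF5 precipitate 3848 were higher and 4650 lower in DM, or 61.2%, and 1399 and 1328 differed at least 2-fold. The split was 2908 to 4655 with median scaling (shift of all genes -0.15), 2639 to 4344 with no scaling (shift -0.16), and turned to 4307 to 4158 with cyclic loess. By gene 2722 were higher and 3080 lower, and 54 genes had probes with opposite calls. Log2 fold changes of DM over GM correlated between the IgG and MYF5 precipitates at Pearson r of 0.951 and Spearman rho of 0.900 across 9429 genes. Both precipitates called 2246 genes higher, against 802 for independent lists, and 2496 lower, against 1048, with 31 opposite calls. The Actb gap was 2.61 in DM against 3.94 in GM with MYF5.

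**Figure D4:**
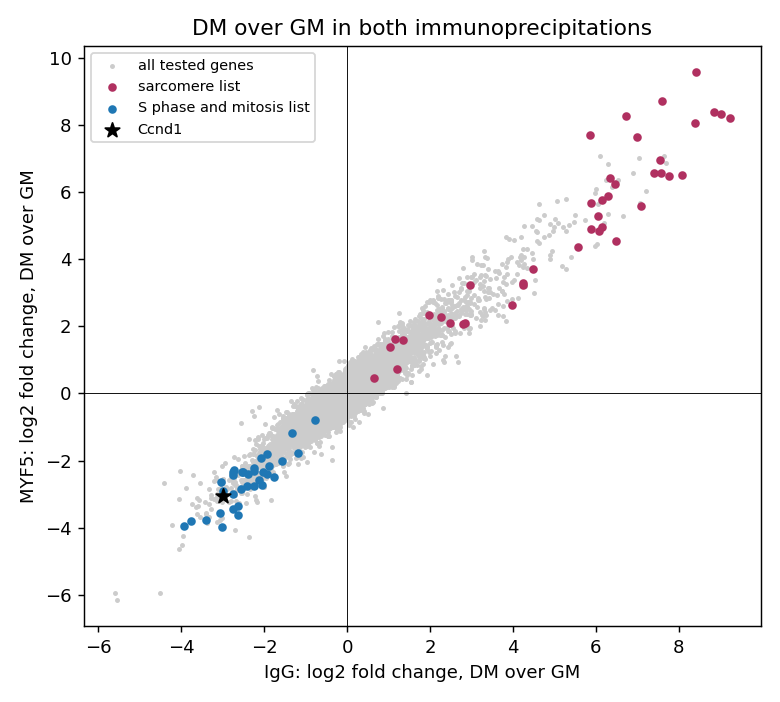
Log2 fold change of DM over GM for each tested gene in the IgG precipitate (horizontal) and the MYF5 precipitate (vertical), with sarcomere genes, S phase and mitosis genes and Ccnd1 marked. The 9429 genes lay along the diagonal at r of 0.951, with Ccnd1 at -3.00 and -3.05.

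Of the lists not past camera between the media, ribosomal proteins missed the threshold with MYF5 alone, at 0.078 (median -0.20). With IgG and with MYF5 respectively, adjusted p was 0.11 and 0.11 for G1 genes (medians -0.53 and -0.50), 0.70 and 0.51 for myogenic regulators (0.04 and 0.26), 0.38 and 0.47 for histones (-0.50 and -0.74), 0.38 and 0.11 for translation factors (-0.17 and -0.27), and 0.38 and 0.30 for RNA-binding regulators (-0.31 and -0.45). Oxidative phosphorylation had 0.80 and 0.13 (medians -0.14 and 0.12, means 0.09 and 0.27), proteasome subunits 0.44 and 0.96 (0.09 and -0.04), secretory genes 0.067 and 0.16 (-0.49 and -0.32), immediate early genes 0.80 and 0.51 (-0.07 and 0.13, means 0.12 and 0.20), cholesterol synthesis 0.38 and 0.34 (-0.38 and -0.18), housekeeping genes 0.11 and 0.16 (-0.49 and -0.40) and the actin list 0.38 and 0.86 (0.19 and -0.17, means 0.32 and 0.09). Adipocyte markers had 0.82 and 0.91, and bone and cartilage markers 0.54 and 0.51.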

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

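Of the tests in this part, those of signal level with gene span, of the scaling for the metabolic and sarcomere patterns, of single Ccnd1 probes, and of splits with the shared antibody effect taken out were chosen after the result was seen.

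Single arrays stood far from the other 3 of their group for 29 of 476 groups of the named genes, or 6.09%. Chance gives about 1 in 20 for independent genes, which genes on 1 array are not. Most of the flags fell on arrays numbered 4, with some for each medium and antibody. Values are the gap to the nearest array over the range of the group. On GM IgG array 4 they were Hba-a1 0.832, Mylpf 0.936, Aldoa 0.936, Eno3 0.957, Frs3 0.849, Prl2c4 0.911, Slco4a1 0.891 and Igsf11 0.950. On GM MYF5 array 4 they were Gadd45a 0.830, Msc 0.921, Mcm5 0.942, Tnnc2 0.846 and Chrng 0.968. On DM MYF5 array 4 they were Eno3 0.919, Myl2 0.951, Psmc4 0.838, Psmc3 0.883 and Actn4 0.962. GM IgG array 2 had Egr2 0.844, Plau 0.876 and Itgb1bp2 0.944, and DM IgG array 2 had Tfdp1 0.861 and Atp5g2 0.882. DM IgG array 4 had Psmc1 0.833, Sgo1 0.847 and the Ccnd1 probe ILMN_2669793 0.853. The rest were Snrnp200 0.879 on GM MYF5 array 1, Myh8 0.855 on GM IgG array 1 and Col1a1 0.860 on GM IgG array 3.

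The fitted change of MYF5 over IgG differed between the media for the genes below, by the test of the DM minus GM difference. Most of them were named because they passed this test, so their share among the named genes says nothing, and over all probes the share was 5.67%. Positive differences were Smarcal1 1.73, H2ac21 1.27, S100a13 0.90, Ddt 0.87, H2ac11 0.91, Hba-a1 1.71, Sprr2a1 0.85, Atrip 1.77, Rpl28 0.60, Jun 0.79, Blm 1.75, H3c10 1.70, Ifitm1 1.56, Myl4 1.53, Gcc2 1.51, Jag1 1.41, Rps13 0.78, Rpl14 0.76, Ndufa4 1.06 and Atp5g2 0.97. Negative differences were Rfc1 -1.62, Stx2 -1.05, Myl2 -1.93, Cox8b -1.58, Myh6 -1.65, Myh4 -1.56, Ckm -1.17, Myh10 -1.19, Chtf18 -1.91, Actn4 -1.75, Itgb1bp2 -1.59, Tceal5 -1.57, Myo5a -1.52, Cdc20 -0.99 and Mcm5 -0.97. Ifitm1 and H3c10 were detected on 0 of the 8 DM arrays and Myl2, Myh6, Itgb1bp2, Cox8b, Tceal5 and Myh4 on 0 of the 8 GM arrays, so for these no change was measurable in that medium. By list the medians that differed were sarcomere -0.47, S phase and mitosis -0.25, ribosomal proteins 0.27, oxidative phosphorylation 0.26 and the actin cytoskeleton -0.15. With an estimated correlation between genes 0 of these 5 lists passed, at adjusted p of 0.52 or 0.80.

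Oxidative phosphorylation, proteasome and ribosomal protein mRNAs were lower with anti-MYF5 in both media. Scaling between arrays, apart from a uniform shift, is argued against. Over 5 scalings, 3 lists and both media the confidence intervals of the list scores ended at most at -0.087 in z units, from the z-scores. On the log2 scale they ended at most at -0.29. The scores are relative to all genes, so a uniform shift cancels in them and was not tested, and median and no scaling gave the same scores. Signal level and gene span are argued against for oxidative phosphorylation and the proteasome, whose medians lay at percentile 0 of matched random lists, and for ribosomal proteins in GM, at percentile 1.23, but not for ribosomal proteins in DM, at 6.49. The lists were not matched on mRNA length, which was not tested. Random lists in this part draw genes that need not move together, so the percentiles do not allow for correlation within a list. With the Actb gap as a covariate at least 74.1% of each difference was left. The slope of that covariate rests on variation within groups of the gap between a single pair of probes. Noise in the gap flattens the slope and leaves more of the difference, so this test cannot decide on RNA quality. Nothing here ties the gap to RNA quality either. RNA quality stays open as a cause, and no biological explanation was tested.

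Ccnd1 was higher with anti-MYF5 in GM, to an extent that hung on the scaling. With quantile or no scaling a fault of 1 probe of Ccnd1 is argued against, since the smallest change of the other probes was 0.44, past the threshold. With median scaling, cyclic loess or z-scores it stays open, since only 1 probe of Ccnd1, ILMN_2669793, was past the threshold. The brightest probe lay at a percentile as low as 56.5 among its 200 neighbours over the 5 scalings. A percentile within the neighbours' spread cannot tell a shared shift from their separate changes. Their median change in GM was 0.13 against 0.55 for Ccnd1 with quantile scaling and 0.21 against 0.43 with median scaling. It was 0.34 against 0.56 with no scaling, -0.02 against 0.19 with cyclic loess, and -0.09 against -0.04 in z units. The medians lay below Ccnd1, and a shift of equally bright probes stays open. Selective recovery by MYF5, the biological explanation, was not tested by these arrays.

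The sarcomere list was lower with anti-MYF5 in DM than in GM, each against its IgG, through members not detected on all 8 GM arrays. Signal at the floor in GM may be the source: the 12 members detected on all 8 GM arrays had a mean difference of 0.27 (SE 0.28), against -0.67 for the other 29. Among the 29, 15 were called lower and 0 higher, and among the 12, 1 lower and 3 higher. Medians of the 12 for MYF5 over IgG were -0.78 in GM and -0.59 in DM. Scaling between arrays cannot be told apart as a source, since the confidence intervals of the list score were not all on 1 side of 0. The score was below 0 under all 5 scalings, at -0.39 with quantile scaling, -0.29 with median or no scaling, -0.24 with cyclic loess and -0.24 in z units. Its interval ended at 0.01 with quantile scaling and at 0.30 with cyclic loess, and lay below 0 with z-scores (-0.42 to -0.05 in z units). Within DM, signal level is argued against, as the list median of -0.89 lay at percentile 0 of random lists matched on DM signal. Differentiation of the cells, the biological explanation, stays untested.

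Other splits of the arrays were counted for each comparison. In GM 1 of 35 splits of the 8 arrays, the real split, gave as many calls (6777, against a highest other of 236). In DM it was 1 of 35 (7346 against 542). For DM over GM it was 1 of 35 with IgG (8719 against 0) and 1 of 35 with MYF5 (8498 against 0). A share of 1 in 35 is the smallest this design allows. Every other split mixes the groups compared, so a real effect moves into the spread within groups and lowers the count. The gaps between these counts therefore do not exclude chance. For the DM minus GM difference 3 of 100 drawn splits gave as many calls as the real 787, with a highest other of 1607. Those splits also move the antibody effect itself, so this share decides nothing about the difference. With the shared antibody effect, as fitted with the real labels, taken out of each probe, 1 of 100 splits gave as many calls. It was the real one (787, against a highest other of 336). Other splits still move the difference itself into the spread within groups, so this count does not exclude chance either.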

How the results depend on the processing

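The fits with the Actb gap as a covariate and without both GM arrays numbered 4 were chosen after the data were seen. A block for the BeadChip was not run, since no file names the chip.

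The brightest Ccnd1 probe, ILMN_1221503, was higher with anti-MYF5 in GM and in DM, and lower in DM than in GM, in every alternative run except the z-scores, where the GM change was reversed at -0.035 in z units. Its DM minus GM difference, not past the threshold in any alternative, changed sign between settings, at 0.28 with cyclic loess and 0.33 with z-scores. Its call in GM was lost with median scaling (0.43) and cyclic loess (0.19), and in DM with median scaling (0.42) and no scaling (0.44). On the log2 scale its range, apart from single arrays left out, was 0.19 to 0.61 in GM and 0.42 to 0.55 in DM. ILMN_2669793 kept its GM call under all 5 scalings, at 0.73 to 1.17 on the log2 scale and 0.45 in z units. In DM both ILMN_2669793 and ILMN_2601471 lost their calls with median scaling and with no scaling. The cause was not tested.

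Counts of called probes stayed within 1.5 times the reported ones for GM (4613 to 7174), DM (5149 to 8562), IgG (6008 to 9521) and MYF5 (5821 to 9233). The DM minus GM count of 787 did not: z-scores gave 1407, no filter 517, array weights 2286, the Actb gap as a covariate 1280, and leaving out the GM arrays numbered 4 gave 1460. Without single arrays it ran from 439 (DM MYF5 array 2) to 1358 (GM IgG array 4), with 513, 478, 494, 466, 457 and 465 without GM IgG arrays 1 and 2, GM MYF5 array 1, DM IgG arrays 1 and 3 and DM MYF5 array 3. The cause was not tested.

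With an estimated correlation between genes the lists past camera went from 9 to 0 in GM, 14 to 0 in DM, 5 to 0 for the difference, 7 to 3 with IgG and 6 to 3 with MYF5. With z-scores those with IgG went from 7 to 11. Apart from single arrays left out, agreement across genes ranged from 0.811 to 0.846 between media and 0.936 to 0.955 between precipitates.

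Without single arrays the counts ran from 6332 to 6924 in GM, 6684 to 7729 in DM, 8234 to 8926 with IgG and 7937 to 8846 with MYF5. Agreement ran from 0.810 to 0.838 between media and 0.943 to 0.953 between precipitates. Ccnd1 ran from 0.49 to 0.68 in GM and 0.43 to 0.57 in DM. Of the calls of named genes 10 were lost in this way, 6 for Atp5g2 and 4 for Rpl14 in the difference, and 0 were reversed. The lists were not rerun without single arrays.

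Among named genes and lists, calls lost numbered 5 with median scaling, 9 with no scaling, 4 with z-scores, 3 with no background correction and 3 with offset 50. The lists were not rerun with no filter or with the Actb gap, where 1 call of a named gene each was lost. After group means were taken out, IgG and MYF5 arrays sharing a number correlated at 0.33, 0.29, 0.01 and 0.61 in GM and 0.37, 0.42, 0.02 and 0.26 in DM. The arrays numbered 3 correlated at only 0.01 and 0.02, so the numbers were not taken as pairs, and not every array correlated best with its own number. The other numbers did share deviations, so a pairing within a medium stays possible. The blocks that were run joined a number across both media, where arrays of the same antibody correlated at -0.14 to 0.29. A block by medium and number was not run. With the replicate number as a fixed block the counts were 7174, 7697, 1158, 9023 and 8838 in the order of the comparisons. Low signal over background limits genes near the floor in 1 medium.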

Other observations

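The tests of gene families in this part were chosen only after the results were seen.

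Grouping genes by the stem of their symbol gave 91 families of at least 10 genes, tested with camera in GM and DM for MYF5 over IgG. Mitochondrial ribosomal proteins were lower, with medians of -0.78 in GM (adjusted p = 8.9e-08) and -0.66 in DM (adjusted p = 9.0e-06) for 43 Mrpl genes, and -0.79 (adjusted p = 1.2e-06) and -0.81 (adjusted p = 1.6e-06) for 27 Mrps genes. With an estimated correlation the 4 adjusted p-values were 0.40, 0.45, 0.40 and 0.35. Mrpl52 changed by -2.11 and -1.44 and Mrpl54 by -2.08 and -1.61, while Mrpl57 went the other way at 1.60 and 1.32, all chosen after their values were seen. The 12 Ift genes of intraflagellar transport were lower, with medians of -0.54 (adjusted p = 0.016) and -0.64 (adjusted p = 0.0063), and adjusted p = 0.46 and 0.37 with an estimated correlation.

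Palmitoyltransferases of the Zdhhc family were higher in DM for 12 of 15 and lower for 0, with a median of 0.62 (adjusted p = 0.0028, and 0.29 with an estimated correlation). In GM they missed the threshold (0.29, adjusted p = 0.052). The 14 Bcl genes had medians of 0.50 (adjusted p = 0.028) and 0.68 (adjusted p = 0.0033), among them Bcl2l1 at 1.22 and 1.13, chosen after its values were seen. With an estimated correlation they had adjusted p = 0.35 and 0.29. Solute carriers, 174 Slc genes, had medians of 0.21 (adjusted p = 0.013) and 0.28 (adjusted p = 3.2e-04), with 0.60 and 0.35 under an estimated correlation. Directions relative to all genes held under the 5 scalings for the families named here.

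The sarcomere gene Mylpf stood highest on the arrays numbered 4 in GM, at 8.02 on GM IgG array 4 against 6.11 to 6.23 on the others, and at 5.51 on GM MYF5 array 4 against 4.57 to 4.75. So did Tnnt1, Tnnc2, Myl1, Actc1 and Dcn, all chosen after their values were seen, with Myl1 at 10.16 against 8.15 to 8.75 for IgG and 8.71 against 6.30 to 7.18 for MYF5. Whether those cells were denser or further differentiated was not tested, which leaves that doubt on the GM values of these genes and on their DM over GM changes. Gene span correlated weakly with the change across 9426 genes, which are not independent replicates (Spearman rho 0.167 in GM and 0.150 in DM).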
